A study of Mus musculus with 6 samples.

How the data were processed

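Retinal RNA was sequenced in 6 samples of C57BL/6 mice aged 8 weeks, 3 named Myrf-kd (Myrf +/−) and 3 wild type (WT), and groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted with Trizol and libraries followed standard Illumina protocols. Whether strand was kept is not given in the sources used here, so reads of overlapping and antisense genes are not told apart. Bowtie 0.12.2, HISAT2 2.0, StringTie 1.3.0 and the build GRCm38 are named in the submitters' processing notes, with no role or order.

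The authors deposited a table of 55450 Ensembl genes with an FPKM and a count for each library. The FPKM columns hold length- and depth-scaled fragment values, per the file headers, with 0.0001 for genes without signal. The counts deposited by the authors were read as estimated counts. They are whole numbers, but for single-transcript genes above 200 units their ratio to FPKM times length lay within 1% of 1 constant per library for 100% of the genes. More genes were listed at 4 units than at 1, 2, 3, 5 or 8, so 4 units were taken as 1 fragment. The counts were already whole, and rounding changed none. WT 2, at 50695091 units, was the shallowest library and WT 3, at 70298511 units, the deepest. All 55450 identifiers matched the GENCODE annotation of GRCm38, 52543 with the same start and end. Coordinates are those of the table.

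Genes with a mean FPKM of at least 1 over the 6 samples were tested. The filter, the gene lists, the rule for named genes, the threshold of 0.05 and a limma fit on log2(FPKM + 1) were fixed before the data were examined. That fit assumed a table of FPKM alone. Since the table also holds counts, edgeR 4.0.16 (quasi-likelihood test, TMM factors, genotype as the only term) on the estimated counts became the main test, and the fit with limma 3.58.1 an alternative. P-values were two-sided with Benjamini-Hochberg adjustment. The SE of a log2 fold change is its size over the root of the F statistic. The biological coefficient of variation was 20.3%, with 2.84 prior degrees of freedom. Myrf lay below the filter and was added to the fit (13674 genes).

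The named genes are Myrf, up to 10 genes per direction and up to 4 members of each list with the smallest p. The genes per direction are those past the threshold with groups that do not overlap and a symbol that is not a predicted name, filled up by the smallest unadjusted p. The 33 lists hold 574 symbols, 1 of them not found in the table, for retinal cell types, neighbouring tissues, pathways and RNA quality. Lists, and GO and KEGG terms of the table with 10 to 300 tested members, were compared with the other genes by limma's camera at a preset correlation of 0.01. An estimated correlation and limma's fry were run beside it.

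No pair of libraries agreed within sampling noise, with a chi-square per degree of freedom of at least 18.4. Alternatives were other filters, pseudocounts, scalings, variance models and term sizes, a replicate block and the omission of each library. Those chosen after seeing the data are named with the results. For Myrf-kd against WT, the tests were run on simulated counts of 13673 genes with 50 genes changed at each size. By edgeR, 0 of 50 genes were recovered at 1.5-fold, 4 at 2-fold, 24 at 3-fold and 30 at 4-fold, and 2 unchanged genes were called. DESeq2 1.42.0 recovered 27 of 50 genes at 2-fold, and 41.8% of its calls were unchanged genes. With no change simulated it called 45 genes, and edgeR 0. The simulated dispersions were drawn around the trend that edgeR estimated, in a single run, and the counts were multiplied by 4. The comparison of the tools may therefore lean towards edgeR. The result of 1 gene is not reported here.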

Results

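RNA of mouse retina was sequenced in 6 samples of the C57BL/6 strain at 8 weeks of age. The labels name 3 samples Myrf-kd, from Myrf +/− mice, and 3 wild type (WT). Myrf encodes a membrane-anchored transcription factor known for driving myelin genes in oligodendrocytes. The estimated counts summed to 64808614, 62092882 and 67766951 units in Myrf-kd 1, 2 and 3 and to 65516550, 50695091 and 70298511 units in WT 1, 2 and 3, with about 4 units per fragment. Levels are given in CPM, the units of a gene scaled to the TMM-normalized library total, with mean ± SD over 3 libraries per group. By Xist and genes of the Y chromosome, Myrf-kd 3 and WT 3 came from females and the other 4 libraries from males. The labels do not say that the samples are separate animals. Each group holds 1 female and 2 male libraries, and so more than 1 animal, but its males may be the same animal. P-values measure only the spread between these samples, part of which may be technical.

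The targeted gene was examined in every library first. Myrf (ENSMUSG00000036098, chromosome 19, 10208272 to 10240748, minus strand, GRCm38) was listed at 0.279, 0.382 and 0.351 FPKM in Myrf-kd 1, 2 and 3. In WT 1, 2 and 3 it was listed at 0.359, 0.397 and 0.463 FPKM, so the groups overlapped. The means were 0.337 ± 0.0526 FPKM in Myrf-kd and 0.406 ± 0.0527 FPKM in WT (SD, n = 3 each). Between 45 and 80 fragments per library lay behind these values. The fitted Myrf level in Myrf-kd was 81.9% of WT, with a 95% interval from 59.6% to 113% (log2 fold change −0.29 ± 0.19 SE). It did not pass the test (adjusted p = 0.732 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). An exact two-sided permutation test gave p = 0.2, and 3 libraries against 3 cannot go below 0.1. A level of 50% lay outside the interval. The labels do not say which part of the gene is altered, and reads summed over the whole gene can include transcripts of an altered copy, so the values do not check the labels.

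Which retinal genes differ between Myrf +/− and wild-type mice was tested over 13673 genes, and 6 genes passed, 4 higher and 2 lower in Myrf-kd. Zfp961 (ENSMUSG00000052446, chromosome 8, 71951038 to 71993792), a zinc finger protein gene, rose 7.70-fold from 3.34 ± 0.591 to 25.7 ± 3.44 CPM. Adam23 (ENSMUSG00000025964, chromosome 1, 63445891 to 63596276), which encodes a membrane protein of the disintegrin type, rose from 19.2 ± 0.740 to 52.6 ± 2.14 CPM. Synpr (ENSMUSG00000056296, chromosome 14, 13284780 to 13615459), which encodes a synaptic vesicle protein, rose 2.21-fold to 229 ± 3.51 CPM. Srp72 (ENSMUSG00000036323, chromosome 5, 76974683 to 76999937), which encodes a subunit of the signal recognition particle, rose 1.56-fold from 99.9 ± 4.71 to 156 ± 5.09 CPM. Flvcr1 (ENSMUSG00000066595, chromosome 1, 191005847 to 191026158), a transporter gene linked to heme and choline, fell from 35.2 ± 2.22 to 10.4 ± 0.855 CPM, a ratio of 0.296. Rnf13 (ENSMUSG00000036503, chromosome 3, 57736062 to 57835231), which encodes a ubiquitin ligase of endolysosomal membranes, fell from 112 ± 5.49 to 48.0 ± 4.6 CPM, a ratio of 0.430.

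By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 fold changes (± SE) were 2.95 ± 0.18 for Zfp961, 1.45 ± 0.08 for Adam23, 1.15 ± 0.06 for Synpr and 0.64 ± 0.06 for Srp72. They were −1.75 ± 0.10 for Flvcr1 and −1.22 ± 0.09 for Rnf13. The adjusted p-values by edgeR were 0.00318 for Synpr, 0.00328 for Zfp961, Adam23 and Flvcr1, 0.00800 for Rnf13 and 0.0427 for Srp72. In each of the 6 genes the 3 Myrf-kd libraries lay on 1 side of the 3 WT libraries. With the replicate number as a block 0 genes passed. The edgeR adjusted p was then 0.0782 for Zfp961 and Synpr, 0.109 for Flvcr1 and 0.227 for Rnf13. Over all alternatives, the log2 fold change lay between 1.87 and 3.06 for Zfp961 and between 1.06 and 1.18 for Synpr. It lay between −1.82 and −1.31 for Flvcr1 and between −1.28 and −1.01 for Rnf13. At an unadjusted p under 0.05 by edgeR there were 1024 genes, 514 higher and 510 lower. The groups did not overlap in 2000 genes (14.6%, where chance gives 10% on average over the splits of the libraries). Genes are not independent, so a single split can lie above that average without an effect of the genotype. Other splits, which mix the genotypes, gave 343 to 990 genes at an unadjusted p under 0.05 by edgeR. The count of 6 became 10 without Myrf-kd 1, 16 without Myrf-kd 3, 10 without WT 1, 10 without WT 2 and 13 without WT 3. Srp72 passed in 1 of 6 omissions of a library, that of Myrf-kd 3 (edgeR adjusted p = 0.0448, and up to 0.204 in the others), and its adjusted p lay between 3.14e-11 and 0.365 over all alternatives. Adam23 did not pass in 8 of 27 alternatives, the limma fit on FPKM among them, with an adjusted p of up to 0.0782 and a log2 fold change down to 0.85.

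**Figure D1:**
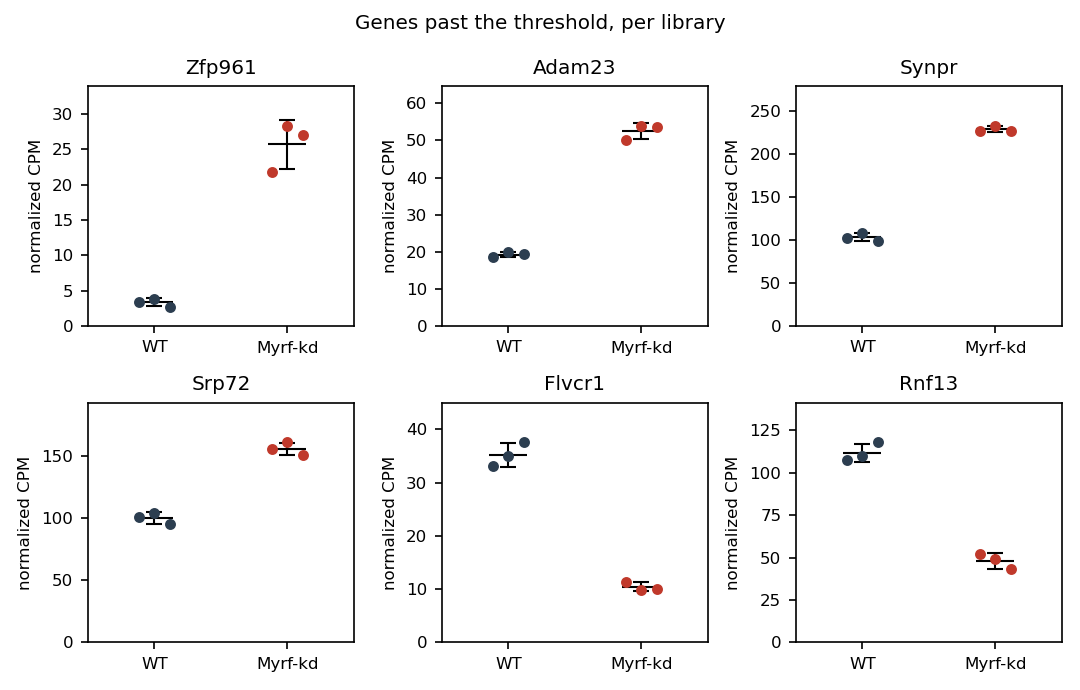
Normalized CPM (vertical axes, starting at 0) of the 6 genes past the threshold in WT and Myrf-kd; each point is a library, the horizontal bar the mean of 3 libraries and the whisker the SD. Zfp961, Adam23, Synpr and Srp72 lay higher in every Myrf-kd library than in any WT library, and Flvcr1 and Rnf13 lower.

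The genes next by unadjusted p did not pass. Of those with a higher estimate in Myrf-kd, the small Maf gene Mafg was at 43.9 ± 4.99 CPM in WT and 78.3 ± 2.97 in Myrf-kd (edgeR adjusted p = 0.110). The dynein light chain gene Dynll1 was at 36.1 ± 1.72 and 61.0 ± 6.24 CPM (edgeR adjusted p = 0.170), and the septin gene Sept8 at 108 ± 13.6 and 177 ± 0.966 CPM (edgeR adjusted p = 0.179). Sept8 passed without WT 2 (edgeR adjusted p = 0.0209), and its adjusted p lay between 2.71e-07 and 0.806 over all alternatives. Zfp738, the peroxiredoxin gene Prdx1 and Uhrf1bp1l had ratios of 1.39, 1.31 and 1.34. Of those with a lower estimate, Wdr13 was at 93.7 ± 1.5 CPM in WT and 64.9 ± 5.91 in Myrf-kd (edgeR adjusted p = 0.348). Tbc1d5 was at 43.5 ± 2.46 and 28.4 ± 3.04 CPM, and Tmem170b at 81.9 ± 6.26 and 57.0 ± 5.10 CPM (edgeR adjusted p = 0.666 for both). Bcar1, Slc25a25, Sult1c1, Epn2 and the translation initiation gene Eif1 had ratios of 0.693, 0.818, 0.453, 0.777 and 0.809.

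Markers of the cornea and surface epithelium, a tissue outside the retina, had the lowest median of the gene lists in Myrf-kd in the main test. In some alternatives the lens median was lower, as with sex as a covariate (−2.25, against −1.72 for the cornea list). All 5 tested members of 13 had lower estimates, with a median log2 fold change of −1.69. On the log2(FPKM + 1) scale of the limma fit, which understates changes of low genes, the median was −0.88, and with quantile normalization −0.89. The keratin gene Krt5 was at 5.18 ± 2.47 CPM in WT and 0.576 ± 0.518 in Myrf-kd. The corneal keratin gene Krt12 was at 5.09 ± 1.35 and 1.09 ± 1.14 CPM, and Aldh3a1, an aldehyde dehydrogenase gene, at 4.37 ± 0.979 and 1.35 ± 0.771 CPM. The list passed with limma's camera (adjusted p = 1.49e-05; adjusted p = 0.223 with an estimated correlation). Over all genes 0 members passed, and 2 members passed adjusted over the list alone. The summed list was at 8.61, 13.2 and 12.2 CPM in Myrf-kd 1, 2 and 3 and 25.6, 35.1 and 24.9 CPM in WT 1, 2 and 3. An exact two-sided permutation test of the log2 sums gave p = 0.1, the smallest possible.

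The summed level of the lens genes was below WT in Myrf-kd 1 and Myrf-kd 2 and highest in Myrf-kd 3. It was 8.33, 6.49 and 89.0 CPM in Myrf-kd 1, 2 and 3 and 26.7, 25.4 and 35.5 CPM in WT 1, 2 and 3 (exact permutation p = 0.5). The list was called lower by limma's camera (adjusted p = 0.0419; adjusted p = 0.896 with an estimated correlation), while the median and mean log2 fold changes of its 8 tested members were positive, 0.22 and 0.41. With other scalings of the counts by edgeR the median lay between 0.216 and 0.255. By limma on FPKM it was −0.404 without rescaling and between −1.19 and −0.401 under other scalings. Of the 8 members 0 passed, over all genes or adjusted over the list alone. The call was lost without Myrf-kd 1 (adjusted p = 0.496 by limma's camera), Myrf-kd 2 (0.667), WT 2 (0.0791) and WT 3 (0.12). It passed in 10 of 25 alternatives, and was lost in the limma fit on FPKM (adjusted p = 0.404 by limma's camera), with median-of-ratios scaling of FPKM (0.559), quantile normalization (0.573) and no filter (0.509). Without Myrf-kd 3 the list was called lower with a median of −6.54 (adjusted p = 2.62e-34 by limma's camera). With sex as a covariate the median was −2.25 (adjusted p = 0.000302), and with the replicate number as a block −2.28 (adjusted p = 6.43e-05, limma's camera).

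**Figure D2:**
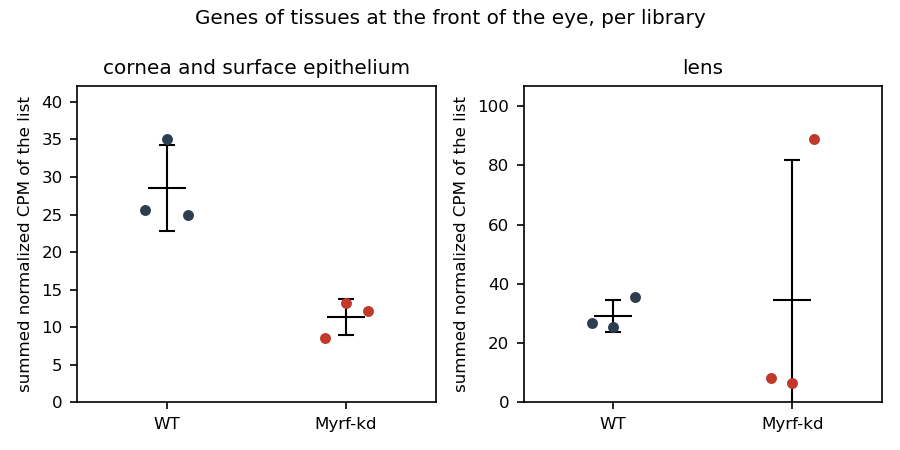
Summed normalized CPM (vertical axes, starting at 0) of the cornea and surface epithelium list and of the lens list in WT and Myrf-kd; each point is a library, the horizontal bar the mean of 3 libraries and the whisker the SD, which runs below 0 for the lens in Myrf-kd. The cornea sums lay at 13.2 CPM or less in Myrf-kd and at 24.9 CPM or more in WT, and the lens sum was 89.0 CPM in Myrf-kd 3.

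Of 24 oligodendrocyte and myelin genes, 5 were tested and the others lay below the filter. All 5 had lower estimates, with a median log2 fold change of −0.35. On the log2(FPKM + 1) scale of the limma fit the median was −0.15, with median-of-ratios scaling −0.16 and with array weights −0.10. The transferrin gene Trf was at 153 ± 16.7 CPM in WT and 118 ± 2.92 in Myrf-kd. The myelin basic protein gene Mbp was at 51.3 ± 3.83 and 46.2 ± 2.55 CPM, and Mal at 12.5 ± 2.95 and 9.44 ± 2.01 CPM. The summed list was at 208, 219 and 199 CPM in Myrf-kd 1, 2 and 3. In WT 1, 2 and 3 it was at 242, 276 and 254 CPM, and Trf weighed most of the named members. RNA of whole retina does not tell which cells made these transcripts, so a change of myelin itself was not tested. The list passed with limma's camera (adjusted p = 0.0239; adjusted p = 0.666 with an estimated correlation). Over all genes 0 members passed, and 1 member, Trf, passed adjusted over the list alone. The call was lost without Myrf-kd 3 (adjusted p = 0.0546 by limma's camera, median −0.17) and without WT 2 (0.0535). It was also lost with no filter, where 22 members were tested (adjusted p = 0.085 by limma's camera). The cornea list, at 11.3 ± 2.4 CPM in Myrf-kd and 28.5 ± 5.68 CPM in WT, was lower in the same libraries.

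Genes of the retinal pigment epithelium had lower estimates in 10 of 13 tested members, with a median log2 fold change of −0.24. The lactate transporter gene Slc16a8 was at 4.11 ± 0.377 CPM in WT and 2.75 ± 0.541 in Myrf-kd. The transthyretin gene Ttr was at 72.5 ± 15.9 and 54.3 ± 10.3 CPM, and the retinoid isomerase gene Rpe65 at 28.1 ± 4.97 and 20.5 ± 7.39 CPM. The list passed with limma's camera (adjusted p = 0.0366; adjusted p = 0.666 with an estimated correlation), with 0 members past over all genes or adjusted over the list alone. Other lists hold 8 of its genes. The call was lost without Myrf-kd 2 (adjusted p = 0.271 by limma's camera, median −0.14) and without WT 3 (0.281, median −0.05), and the median was −0.15 without Myrf-kd 3. It was also lost with median-of-ratios scaling of FPKM (adjusted p = 0.0749 by limma's camera), quantile normalization (0.0686) and a mean FPKM of at least 5 (0.235). The summed list was at 457, 423 and 528 CPM in Myrf-kd 1, 2 and 3. In WT 1, 2 and 3 it was at 483, 508 and 551 CPM, so the groups overlapped. Those of the summed cornea list did not, at most 13.2 CPM in Myrf-kd and at least 24.9 CPM in WT.

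Genes of the unfolded protein response had lower estimates in 15 of 20 members, with a median log2 fold change of −0.12. The summed list was at 2780, 2470 and 2050 CPM in Myrf-kd 1, 2 and 3. In WT 1, 2 and 3 it was at 2600, 2750 and 2460 CPM, so the groups overlapped. The chaperone gene Hspa5 was at 298 ± 21.0 CPM in WT and 250 ± 17.7 in Myrf-kd, and Ddit3 at 82.5 ± 6.89 and 62.7 ± 15.8 CPM. The list passed with limma's camera (adjusted p = 0.0366; adjusted p = 0.802 with an estimated correlation). Cell death genes had lower estimates in 7 of 9 tested members, with Phlda3 at 4.18 ± 0.457 CPM in WT and 2.94 ± 0.364 in Myrf-kd and Cdkn1a at 19.5 ± 2.37 and 12.4 ± 5.58 CPM. That list passed with limma's camera (adjusted p = 0.0432; adjusted p = 0.666 with an estimated correlation). Both lists had 0 members past over all genes or adjusted over the list alone. Myrf-kd 3 held the lowest levels of Ddit3 (44.6 CPM) and Cdkn1a (6.53 CPM). It stood apart on the first principal component (28.9% of the variance), at 43.8. WT 3, the other female library, was at 10.8, and the male libraries lay between −17.3 and −6.48. Myrf-kd 3 is the only female Myrf-kd library, so a part of sex in this is not told apart. On the second component (22.5% of the variance), Myrf-kd 1, 2 and 3 were at 10.2, 25.7 and 11.5. WT 1, 2 and 3 were at 3.07, −21 and −29.5 there, and no test of the components was run. By limma's camera the unfolded protein response was lost without Myrf-kd 2 (adjusted p = 0.152), Myrf-kd 3 (0.0546), WT 2 (0.171) and WT 3 (0.0573). Its median was −0.06 without Myrf-kd 2, −0.07 without WT 2, −0.19 without Myrf-kd 1 and −0.20 without WT 1. It was also lost with median-of-ratios scaling of FPKM (adjusted p = 0.0749 by limma's camera), quantile normalization (0.0934), array weights (0.0533) and male libraries only (0.0709). Cell death was lost without Myrf-kd 2 (adjusted p = 0.271 by limma's camera), Myrf-kd 3 (0.0886), WT 1 (0.11), WT 2 (0.0866) and WT 3 (0.0573). It passed in 14 of 27 alternatives, with an adjusted p of up to 0.376 by limma's camera, and its median of −0.13 became −0.26 without Myrf-kd 1 and −0.28 without WT 3.

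Cholesterol synthesis genes had higher estimates in 16 of 20 members, with a median log2 fold change of 0.14. The summed list was at 1400, 1570 and 1360 CPM in Myrf-kd 1, 2 and 3. In WT 1, 2 and 3 it was at 1400, 1270 and 1340 CPM, so the groups overlapped. The mevalonate kinase gene Mvk was at 12.6 ± 1.39 CPM in WT and 15.9 ± 1.98 in Myrf-kd, Stard4 at 35.2 ± 1.64 and 42.2 ± 5.77 CPM, and Cyp51 at 65.3 ± 1.38 and 71.4 ± 2.60 CPM. The list passed with limma's camera (adjusted p = 0.0368; adjusted p = 0.802 with an estimated correlation), with 0 members past over all genes or adjusted over the list alone. The call was lost without Myrf-kd 2 (adjusted p = 0.667 by limma's camera, median 0.08), WT 2 (0.158) and WT 3 (0.064), and with no filter (0.072).

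Of 33 lists, 7 passed with limma's camera at a preset correlation of 0.01, 6 called lower and 1 higher. With an estimated correlation 0 passed (1 at an unadjusted p under 0.05), and limma's fry called 0 (2 at an unadjusted p under 0.05). The count of 7 became 2 without Myrf-kd 2, 4 without WT 2 and 2 without WT 3. On simulated counts, a set of 20 genes raised 1.5-fold passed at the preset correlation (adjusted p = 3.39e-10 by limma's camera). With an estimated correlation the same set did not pass (adjusted p = 0.0971), so failing there does not show that a list is unchanged. Genes were simulated independently, so the preset correlation was not put to a test.

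Genes of retinal neurons and glia were on lists that did not pass. The rod list had 14 members higher and 16 lower, with an adjusted p of 0.787 by limma's camera. The cone list (adjusted p = 0.856 by limma's camera) held the opsin gene Opn1sw, at 370 ± 8.26 CPM in WT and 431 ± 48.2 in Myrf-kd. The rod gene Rp1 was at 520 ± 15.4 and 611 ± 70.5 CPM, the amacrine gene Pax6 at 179 ± 5.45 and 209 ± 23.6 CPM, and the synaptic scaffold gene Dlg4 at 827 ± 70.2 and 703 ± 33.6 CPM. These 4 genes did not pass (edgeR adjusted p = 0.666). Adjusted p-values by limma's camera were 0.561 for the ribbon synapse, 0.532 for bipolar, 0.856 for amacrine, 0.928 for horizontal and 0.856 for retinal ganglion cells. They were 0.717 for Mueller glia, 0.908 for astrocytes and 0.873 for microglia and macrophages.

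Genes linked to eye size had 5 of 9 tested members higher and 4 lower (adjusted p = 0.856 by limma's camera). Tmem98, a transmembrane protein gene, was at 12.8 ± 0.734 CPM in WT and 11.8 ± 0.367 in Myrf-kd (edgeR adjusted p = 0.762), and Crb1, a cell polarity gene, at 406 ± 10.9 and 494 ± 93.0 CPM. Of the pathway lists that did not pass, adjusted p-values by limma's camera were 0.0788 for the circadian clock, 0.106 for reactive gliosis, 0.126 for the visual cycle and 0.455 for the interferon response. They were 0.547 for melanin synthesis, 0.552 for nuclear OXPHOS, 0.856 for heat shock and 0.908 for immediate early genes. Of the neighbouring tissues, they were 0.208 for blood, 0.371 for endothelium and mural cells, 0.397 for fibroblasts and scleral matrix, 0.572 for skeletal muscle and 0.787 for the ciliary body and iris. Cytosolic ribosomal protein genes had 0.217 and mitochondrially encoded genes 0.306.

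Of 3054 annotation terms, 0 passed with limma's camera, and 187 had an unadjusted p under 0.05, 161 lower and 26 higher. The limma fit on FPKM called 0 as well. The lowest adjusted p by limma's camera, 0.382, was that of protein digestion and absorption (36 members), negative regulation of DNA binding (21 members) and limb morphogenesis (14 members), each called lower. The count of 0 became 3 without Myrf-kd 1, 1 without Myrf-kd 2 and 2 without Myrf-kd 3.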

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

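The tests of this part were chosen after the result was seen, except the counts over splits of the libraries.

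Gm43181 (ENSMUSG00000106609, chromosome 5, 43784046 to 43786117, minus strand), a gene under the expression filter, had at least 23 units in each Myrf-kd library (29, 23 and 64) and 2, 0 and 4 units in WT 1, 2 and 3. Gm17114, listed as an overlapping noncoding RNA, went the other way, with 1 unit in each Myrf-kd library and 22, 24 and 25 units in WT. At about 4 units per fragment both genes rest on few fragments, near the floor. Whether strand was kept is not given, so reads of Gm17114 and of genes it overlaps are not told apart. Both were chosen after their values were seen, by at least 20 units in each library of a group and at most 4 in each of the other, and another split of the libraries gave 4 such genes.

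The 6 genes past the threshold could stem from reads moved between neighbouring genes or from alleles carried along with Myrf. The first is argued against, since 0 of the 6 had a gene within 30 kb that moved the opposite way by at least 50% of its difference, the highest being 6.54% for Paics beside Srp72. The second is argued against only for alleles that change genes of chromosome 19 itself, since 0 of the 6 lie there. Of its 471 genes, 5.10% had an unadjusted p under 0.05 by edgeR, against 7.49% of all genes. A short segment around Myrf was not examined apart from the whole chromosome. In 3 of 10 splits, the real one included, at least as many genes passed, 6 in the real split and 7 in the highest other. Every other split sets 2 libraries of 1 genotype against 1, so it is not free of a genotype effect. Also, 10 splits are too few for a share under 0.05. An effect of the genotype stays open. So do alleles on other chromosomes and alleles carried with Myrf that act on genes elsewhere, which were not tested.

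The lower cornea list may come from less corneal epithelium carried over with the Myrf-kd retinas, or from the genotype. Of 8 members under the filter, 6 (75%) were lower in Myrf-kd too, which both would give, so this does not decide between them. A piece of the front of the eye that carries lens and cornea together stays open as well. Lens and cornea sums were both below every WT library in Myrf-kd 1 and Myrf-kd 2, while 1 library, Myrf-kd 3, had a lens sum of 89.0 CPM, above every WT library, and a cornea sum of 12.2 CPM, below every WT library.

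Over the same splits, 3 of 10, the real one included, gave at least as many lists, 7 in the real split and 9 in the highest other. Again, 10 splits are too few for a share under 0.05. For terms, the real split gave 0, so that all 10 of 10 splits gave as many by construction and the comparison decides nothing; the highest other gave 20. The split with 20 terms set Myrf-kd 1, Myrf-kd 2 and WT 1 against the rest.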

How the results depend on the processing

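The tests with DESeq2, robust edgeR, library totals, counts divided by 4, sex as a covariate and male libraries only were chosen after seeing the data; the limma fit on FPKM was fixed before, and became an alternative after. Myrf stayed lower and not past the threshold in 27 of 27 alternatives (log2 −0.38 to −0.03, and −0.38 to −0.17 with a library left out); it was not tested at a mean FPKM of at least 5. The count of 6 genes stayed within 1.5 times in 20 of 30 alternatives. It was 2 at a mean FPKM of at least 5 (7647 genes tested), 76 at an unadjusted p under 0.05 and 2-fold, 22 in male libraries only, 53 by DESeq2, and 9 to 16 with a library left out; the limma fit gave 4. Of 28 sets of called genes, 9 held all 6 genes and 10 held 5. The count of 7 lists was 0 with an estimated correlation, 0 by directional fry, 0 by mixed fry, 3 with median-of-ratios scaling of FPKM, 3 with quantile normalization, 4 with no filter, 3 at a mean FPKM of at least 5, and 2 to 9 with a library left out. The cornea list passed in 26 of 26 alternatives at the preset correlation that tested it, which leaves out a mean FPKM of at least 5, and did not pass with an estimated correlation (adjusted p = 0.223 by limma's camera). The count of 0 terms was 3 with terms of 5 to 500 members, each holding Flvcr1, 1 with no filter, 1 at a mean FPKM of at least 0.1, 1 in male libraries only, and 0 to 3 with a library left out. Apart from fewer genes or samples, the cause was not tested. Camera has no option for limma's robust variance, so lists and terms were not run with it, nor with DESeq2; robust edgeR was run for both.

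With the replicate number as a block, 0 genes passed by edgeR (702 at an unadjusted p under 0.05, and 6 without the block), 7 lists and 0 terms. Pairing by number was not seen, with correlations of deviations of −0.048, 0.015 and 0.095. Of 6 libraries, 2 correlated best with their own number. With 3 libraries per group these values cannot exclude pairing. Number 3 was female and numbers 1 and 2 male in both groups. Of 4109 values of named genes, 4060 kept their side of the threshold, 31 no longer passed and 18 newly passed. Most named genes lay far from the threshold in the main test, so the total says little about the called genes. Srp72 no longer passed in 19 of 28 alternatives and Adam23 in 8 of 27. Zfp961, Synpr, Flvcr1 and Rnf13 no longer passed in 1 each. The sign turned in 0 values past the threshold, and did turn for genes not past it, such as Fbln1 (log2 −0.25 to 2.93). Depth limits weakly expressed genes, such as Myrf with 45 to 80 fragments per library.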

Other observations

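The genes of this part were chosen after their values were seen, no tests were added for them, and none passed over all genes.

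Single genes had their lowest or highest level in Myrf-kd 3, the only female Myrf-kd library. The transcription factor gene Atf3 was at 34.5, 27.7 and 7.32 CPM in Myrf-kd 1, 2 and 3 and at 46.5, 40.6 and 44.7 CPM in WT 1, 2 and 3. Trib3 was at 23.3, 18.1 and 7.32 CPM in Myrf-kd and at 27.2, 26.9 and 25.8 CPM in WT. The metallothionein gene Mt2 was at 26.9, 21.8 and 11.2 CPM in Myrf-kd and at 32.4, 33.3 and 27.6 CPM in WT. In the other direction, the heat shock gene Hspa1a was at 53.6 CPM in Myrf-kd 3 and at most 36.4 CPM in the other 5 libraries, and the immediate early gene Fos at 37.2 CPM and at most 26.2 CPM. Of 19 circadian clock genes, 5 had lower estimates at an unadjusted p under 0.05 and 0 higher ones, with 0 past adjusted over the list alone. Among them were Ciart, at 17.97 to 25.9 CPM in Myrf-kd and 28.96 to 31.4 CPM in WT, and Arntl, at 129 to 158 CPM and 172 to 177 CPM.

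Other genes differed within a group. Bsn, which encodes a presynaptic scaffold protein, was at 90.1, 191 and 78.6 CPM in WT 1, 2 and 3 and at 189, 226 and 169 CPM in Myrf-kd 1, 2 and 3. The matrix gene Fbln1 was at 35.0 CPM in Myrf-kd 1 and at most 3.38 CPM in the other 5 libraries. The rod gene Esrrb was at 742 CPM in Myrf-kd 3 and at most 277 CPM in the others.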
